A study of Homo sapiens with 78 samples.

How the data were processed

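RNA was measured in 13 clones of HEK293/hTLR4A-MD2-CD14, a human embryonic kidney line that expresses the LPS receptor TLR4 and its partners MD2 and CD14. Per the labels' protocols, LPS was added at 1 ug/mL a day after plating, RNA was treated with DNase and enriched for messenger RNA, and cDNA was made by a scaled-down full-length method and tagmented. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR to GRCh37 and assigned to genes with featureCounts. The versions, the annotation release, any use of strand and any filter are not given in the sources used here. The deposited table holds raw read counts per gene, as whole numbers.

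The table held 56238 genes and 78 libraries, and 0 columns were left without a sample. Total counts per library were 7534370 to 23934167, with a median of 15913216, and 15688 genes had no read in any library. Symbols came from a table of gene IDs for 50900 genes and from GENCODE for 304 more, and 5034 IDs stayed without a name. GENCODE and RefSeq are on another genome build than the counts, so no coordinate was used. They gave chromosome names, transcript lengths and GC content only.

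The clone, not the culture, was the unit of replication. Counts of the 2 cultures of each clone and condition were summed, which gave 39 clone libraries of 20346885 to 42775282 counts. CPM, counts scaled to library size, were computed from the deposited counts with TMM factors. Log2 fold changes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM normalisation, robust quasi-likelihood fits and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The 3 LPS comparisons fitted clone and condition over all 13 clones. The 6 genotype comparisons were fitted within each condition, and the 4 response comparisons tested whether the change from control differed between genotypes, with clone in the model. The standard error of a log2 fold change was derived from edgeR's F statistic, and intervals cover 95%. Where a gene had few control reads, that standard error does not measure how precisely its fold is known. Per-clone responses were log2 CPM with a prior count of 2, LPS minus control.

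The comparisons, the 24 gene lists and the rule for named genes were fixed before the data were examined. The rule named IRF1, IRF1-AS1, TLR4, LY96 and CD14 throughout. For LPS it added the 12 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean CPM of at least 5 and the same direction in at least 12 clones. For genotype it allowed up to 10 genes in each direction with a mean CPM of at least 1, or, where no gene passed, the 3 with the smallest p. The lists covered NF-kB target genes, cytokines and chemokines, immediate early and AP-1 genes, interferon-stimulated genes, IRF1-associated and antigen presentation genes, TLR4 pathway components and the neighbourhood of IRF1. They also covered cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, DNA replication, mitosis, the unfolded protein and integrated stress response, p53 targets, cholesterol synthesis, hypoxia and glycolysis, and heat shock. The last were replication-dependent histones, nuclear RNA, and markers of monocytes, lymphocytes, fibroblasts, simple epithelium and neuronal or embryonic kidney cells. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1), adjusted over the lists of a comparison.

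Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, a mean CPM of at least 5, and unsummed libraries in limma voom with clone as a random effect, with and without the replicate number as a block. Others left out each replicate number or each clone, put all 9 groups in 1 fit, used only the genotypes compared, used only clones whose name starts with 1-, or fitted a trend from WT over HE to HO. Equal weight to both cultures, and leaving out 2 clones low in TLR4, were added after the data were seen. Genotype labels were moved between clones, and conditions swapped within clones, in up to 100 splits per comparison. Per-clone responses of IRF1 and 4 lists were compared with two-sided exact permutation tests, and relations between clones with 100000 permutations.

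The main test was tested on simulated counts drawn from the real means and library sizes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The changed genes were taken only from those with an average CPM of at least 5, and genes were simulated independently of each other. Recovery of genes below that level was not tested, so the shares do not hold for all genes tested. For LPS at 90 min over 19189 genes it recovered 95.5%, 100% and 100% of them, with 13 false calls. For HO against WT in control, over 16822 genes, it recovered 8.96%, 74.6% and 98.5%, with 5 false calls. For HE against WT in control, over 16943 genes, it recovered 5.97%, 62.7% and 98.5%, with 6 false calls. For the HO response at 90 min, over 19270 genes, it recovered 14.9%, 50.7% and 98.5%, with 5 false calls.

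Reads of near-identical genes can be shared, which makes the split between CXCL1, CXCL2 and CXCL3, between HSPA1A and HSPA1B, among HLA and histone genes, and between mitochondrial genes and their nuclear copies uncertain. IRF1-AS1 and ZNF503-AS2 are antisense or neighbouring transcripts, and with no stated use of strand their reads cannot be separated from those of an overlapping partner. Reads of TLR4, LY96 and CD14 can come from the introduced or the native gene. No molecular identifiers are described, so reads are not independent molecules, and the intervals given rest on the spread between clones.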

Results

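The series measured messenger RNA in clones of a TLR4-expressing HEK293 line that had been edited at a locus whose variant is associated with distant genes of the immune response. It asked whether the edit alters how the cells answer LPS, a component of bacterial outer membranes sensed by TLR4. The labels gave 5 clones as WT, 3 as HE and 5 as HO, read here as unedited, heterozygous and homozygous, which the labels do not spell out. All WT clones had names starting with 1-, as did the HO clones except 2-H1, while the HE clones were 2-C10, 3-E1 and 3-F12. HE against WT therefore cannot be told apart from that prefix, whose meaning is not given. Taking only clones named 1- leaves no HE clone. Each clone was sampled without LPS, after 90 min and after 12 h of LPS at 1 ug/mL, in 2 cultures, for 78 libraries in 9 groups. The WT and HO groups held 10 libraries each and the HE groups 6. Median totals were 15585931 counts in control, 12475294.5 at 90 min and 17557728 at 12 h, and library totals ran from 7534370 to 23934167. TLR4 was at 4.28 to 12.5 CPM in the WT clone 1-G8 and the HO clone 1-F12, and at 72.2 to 194.7 CPM in the other 11. Values are per clone, with both cultures summed.

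After 90 min of LPS, several chemokine genes, TNF and NFKBIA rose in all 13 clones. CXCL8, which codes for the neutrophil attractant IL-8, went from 0.310 ± 0.330 CPM (SD, n = 13 clones) in control to 48.8 ± 56.1 CPM. TNF, the gene of tumour necrosis factor, went from 0.0159 ± 0.0572 to 8.96 ± 4.44 CPM. NFKBIA, which codes for an inhibitor that holds NF-kB in the cytoplasm, rose by 5.18 ± 0.24 log2 units (standard error, n = 13 clones) from 36.4 ± 5.22 to 1494 ± 668 CPM. IRF1, a transcription factor of interferon and antigen presentation genes, rose by 1.82 ± 0.13 log2 units in 13 of 13 clones, from 6.02 ± 1.39 to 22.1 ± 8.17 CPM (edgeR adjusted p = 3.99e-13).

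Over all genes tested with edgeR, 1181 rose and 1087 fell among 19526 at 90 min. Of these, 148 rose and 13 fell at least 2-fold. In the cytokine and chemokine list, 11 of 20 tested members rose, 0 fell and 9 did not pass (camera adjusted p = 1.77e-11 with an estimated correlation). The largest rises by the rule were in the chemokine genes CXCL1, by 10.14 ± 0.35, and CXCL2, by 9.46 ± 0.27 log2 units, then TNF, by 8.91 ± 0.30, CXCL8, by 7.23 ± 0.28, and CCL20, by 6.57 ± 0.40. These folds rest on few control reads, 26 for CXCL1, 65 for CXCL2, 6 for TNF, 124 for CXCL8 and 78 for CCL20 over the 13 clones. For TNF, 12 of the 13 clones had no control read. The folds depend on the prior count of the fit. Their standard errors, derived from the F statistic, do not measure how precisely they are known. In the NF-kB target list, 23 of 38 members rose, 0 fell and 15 did not pass (adjusted p = 8.36e-09 with an estimated correlation). Among them TNFAIP3, which codes for the ubiquitin-editing inhibitor A20, rose by 5.51 ± 0.18, NFKBIZ, a nuclear modulator of NF-kB, by 4.92 ± 0.24, IER3, an early survival gene, by 3.58 ± 0.22, and TNFRSF9, a TNF receptor family member, by 2.76 ± 0.32. Of the immediate early and AP-1 genes, 28 of 37 rose, 0 fell and 9 did not pass (adjusted p = 1.12e-07 with an estimated correlation), with JUNB by 2.80 ± 0.19 and JUN by 2.48 ± 0.19, both AP-1 subunits.

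Falls at 90 min were smaller. ID3 and ID1, inhibitors of helix-loop-helix transcription factors, fell by 0.80 ± 0.11 and 0.71 ± 0.11 log2 units, and TOB1, an antiproliferative gene, fell by 0.76 ± 0.08 in 13 of 13 clones (edgeR adjusted p = 1.73e-08). The developmental transcription factor genes ZIC2, TGIF1 and ALX1 fell by 0.89 ± 0.14, 0.82 ± 0.13 and 0.67 ± 0.10, and the potassium channel gene KCNJ8 fell by 0.66 ± 0.10. ENSG00000117289, an ID that the annotation sources used here did not name, fell by 1.13 ± 0.14. In the mitosis and G2 list 19 of 40 members fell, 0 rose and 21 did not pass (adjusted p = 0.0190 with an estimated correlation), among them CDK1, the mitotic kinase, by -0.46 ± 0.10, and TOP2A, a topoisomerase, by -0.34 ± 0.07. Of the TLR4 pathway components, 6 of 30 rose and 2 fell, with the adaptor gene TICAM1 at 1.12 ± 0.16 and LY96, the gene of MD2, at 0.49 ± 0.14 (camera adjusted p = 0.137 for the list). CD14, the LPS co-receptor, changed by 0.09 ± 0.15 and IRF1-AS1, annotated antisense to IRF1, by -0.08 ± 0.21, and neither passed.

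Interferon-stimulated genes were mixed at 90 min, with 2 of 40 members up, 3 down and 35 not passing (camera adjusted p = 0.802). Of the IRF1-associated and antigen presentation genes 3 of 35 rose and 2 fell. In the list of IRF1's neighbourhood 1 of 22 rose, which was IRF1 itself (camera adjusted p = 0.793 for both lists). Camera calls for ribosomal protein genes (0 of 74 past the threshold) and nuclear oxidative phosphorylation genes (2 up and 8 down of 58) were lost at adjusted p = 0.868 and 0.826 with an estimated correlation. TLR4 itself rose by 0.22 ± 0.07 (edgeR adjusted p = 0.0406), but only 7 of 23 alternatives kept that call, with adjusted p from 0.0102 to 0.843. With only the cultures numbered 1 the test called 506 genes, limma voom on unsummed libraries with clone as a random effect 1258, edgeR without the 2 clones low in TLR4 1271, and ID1 lost its call in 2 of 23 alternatives (edgeR or limma adjusted p from 8.46e-13 to 0.980). LY96 lost its call in 4 of 23 (adjusted p from 2.41e-06 to 0.766) and was 0.16 without replicate 1.

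**Figure D1:**
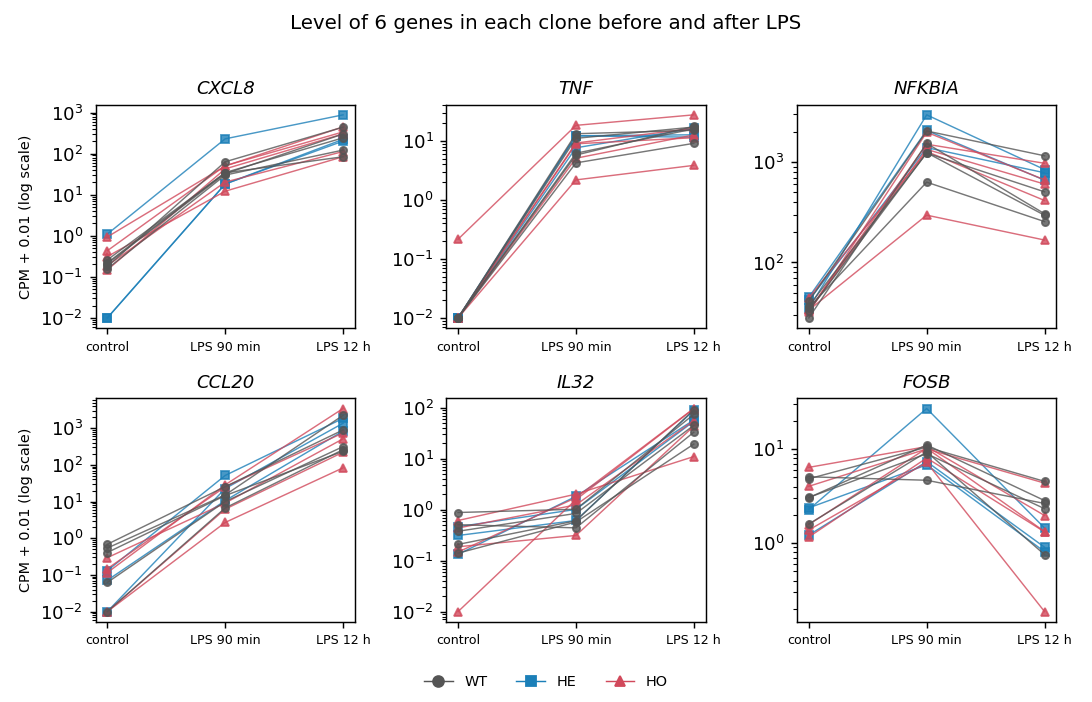
Level of 6 genes in each of the 13 clones (points joined by lines, coloured by genotype) in control and after LPS, as CPM plus 0.01 on a log axis. CXCL8, TNF, CCL20 and IL32 lay higher at 12 h than in control in every clone, and FOSB was higher at 90 min (mean 10.2 CPM) than at 12 h (mean 1.95 CPM).

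After 12 h of LPS the clones carried a late inflammatory programme. Each clone had a single untreated condition, with no time given and no control matched to each LPS time. In every LPS comparison, and between the times, changes with time in culture therefore cannot be told apart from those of LPS. CCL20, which codes for an attractant of lymphocytes and dendritic cells, went from 0.182 ± 0.223 CPM (SD, n = 13 clones) in control to 1002 ± 992 CPM, and CXCL8 reached 290 ± 215 CPM. IL32, the gene of a proinflammatory cytokine, went from 0.330 ± 0.240 to 59.2 ± 28.9 CPM. TNC, the gene of the matrix protein tenascin C, rose by 4.10 ± 0.28 log2 units (standard error, n = 13). IRF1 was still raised, by 1.37 ± 0.13 log2 units in 13 of 13 clones (edgeR adjusted p = 2.36e-10).

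At 12 h edgeR called 1397 genes as raised and 1524 as lowered among 19526, with 234 and 180 at least 2-fold. Of the cytokines and chemokines 14 of 20 rose, 0 fell and 6 did not pass (adjusted p = 7.25e-13 with an estimated correlation). CCL20 rose by 12.11 ± 0.42 log2 units, CXCL8 by 9.94 ± 0.29, TNF by 9.66 ± 0.29, CXCL1 by 8.99 ± 0.35, IL32 by 7.30 ± 0.37 and CXCL2 by 7.28 ± 0.27. These folds also rest on few control reads, and their standard errors do not measure how precisely they are known. Of the NF-kB targets 32 of 38 rose, 0 fell and 6 did not pass (adjusted p = 4.69e-10 with an estimated correlation). TNFRSF9 rose by 6.47 ± 0.30, TNFAIP3 by 4.05 ± 0.17, NFKBIA by 3.79 ± 0.22 and NFKBIZ by 3.70 ± 0.23, and CALCB, a calcitonin gene-related peptide, rose by 3.98 ± 0.29. IRF1-associated and antigen presentation genes rose in 12 of 35 members, fell in 1 and did not pass in 22 (adjusted p = 2.26e-05 with an estimated correlation). They included TAPBP, the tapasin gene of peptide loading, at 1.80 ± 0.13, the peptide transporter gene TAP1 at 0.99 ± 0.10, and HLA-B at 0.74 ± 0.10. Heat shock genes rose in 9 of 19 members and fell in 1 (adjusted p = 0.00378 with an estimated correlation), with the chaperone genes HSPA8 at 0.95 ± 0.11 and HSPA1A at 0.96 ± 0.11, while HMOX1, heme oxygenase, was at -0.99 ± 0.16.

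Of the genes with the largest falls at 12 h by the rule, MAP2K6, an activator of p38 MAP kinase, fell by 1.75 ± 0.21 log2 units in 13 of 13 clones (edgeR adjusted p = 2.62e-07), LGR5, a receptor that enhances Wnt signalling, by -1.48 ± 0.13, and ID2 by -1.28 ± 0.10. UNC5C, a netrin receptor, was at -1.61 ± 0.28, ZNF503 and ZNF503-AS2 at -1.25 ± 0.14 and -1.37 ± 0.15, the homeobox gene HOXA5 at -1.20 ± 0.09, and LAMA4, a laminin chain, at -1.19 ± 0.16. The receptor partners LY96 and CD14 rose by 1.16 ± 0.14 and 1.03 ± 0.16 log2 units, while TLR4 was at 0.17 ± 0.07 and did not pass (edgeR adjusted p = 0.110). Of the TLR4 pathway components 5 of 30 rose and 1 fell, a camera call (adjusted p = 0.0152) that was lost at adjusted p = 0.129 with an estimated correlation. In the neighbourhood of IRF1, 4 of 22 members rose, IRF1, SHROOM1, SEPTIN8 and HSPA4, and 2 fell, KIF3A by -0.32 ± 0.07 and IRF1-AS1 by -0.82 ± 0.21 (camera adjusted p = 0.615 for the list).

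Interferon-stimulated genes were again mixed at 12 h, with 5 of 40 up, 3 down and 32 not passing (adjusted p = 0.881), OAS3, an antiviral enzyme, at 1.14 ± 0.16 and IFIT1 at -1.09 ± 0.17. Across genes, the change at 12 h had a Spearman rho of -0.17 with transcript length, against -0.0039 at 90 min. With the cultures of a single replicate number 1873 genes (without replicate 1) or 1720 were called, of which 1361 and 1561 were shared with the 2921. CD14 at 12 h lost its call in 1 of 23 alternatives (adjusted p from 5.91e-31 to 0.0571), and IRF1-AS1 in 1 of 22, at -0.62 without replicate 2 (adjusted p from 0.00105 to 0.283).

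**Figure D2:**
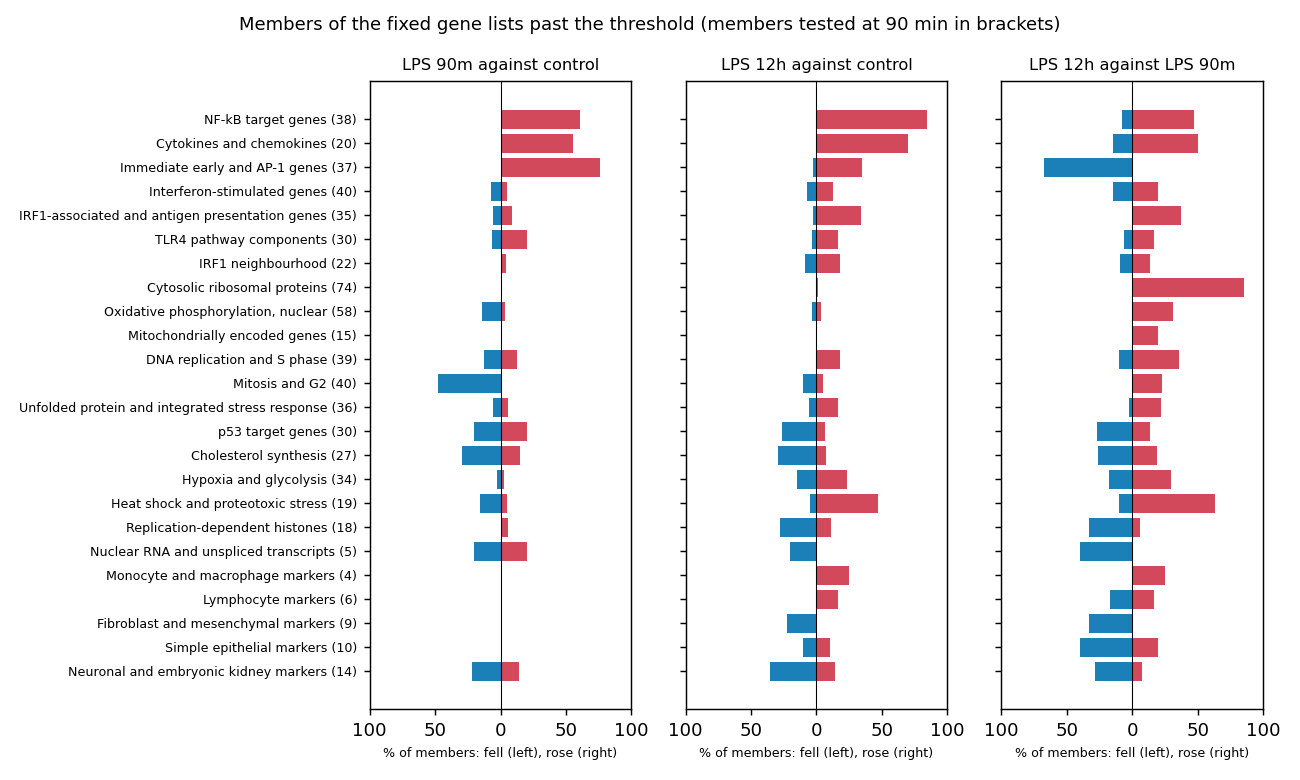
Share of the tested members of each of the 24 gene lists that rose (right) or fell (left) past the threshold in each LPS comparison, with the number tested at 90 min in brackets. Of the 37 immediate early genes 28 rose at 90 min and 25 fell between 90 min and 12 h, while 32 of the 38 NF-kB targets were raised at 12 h.

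From 90 min to 12 h most immediate early genes fell. Over the same interval 10 of 20 cytokine genes and 13 of 35 IRF1-associated and antigen presentation genes rose. FOSB, an AP-1 subunit, went from 10.2 ± 5.42 CPM (SD, n = 13 clones) to 1.95 ± 1.35 CPM, and EGR1, a growth-response transcription factor, from 18.4 ± 9.74 to 3.83 ± 3.17 CPM. IL32 went from 1.05 ± 0.569 to 59.2 ± 28.9 CPM, and CD44, an adhesion receptor, from 15.5 ± 5.93 to 124 ± 79.2 CPM. IRF1 fell by 0.45 ± 0.12 log2 units between the times, in 11 of 13 clones (edgeR adjusted p = 0.00915).

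Between the times edgeR called 1998 genes higher and 2012 lower at 12 h among 19526, with 164 and 309 at least 2-fold. Without replicate 1 it called 2114 genes and without replicate 2 it called 2246, against 4010. Of the immediate early and AP-1 genes 25 of 37 fell, 0 rose and 12 did not pass (adjusted p = 0.000624 with an estimated correlation). FOSB fell by 2.57 ± 0.26 log2 units, EGR1 by -2.48 ± 0.27, PPP1R15A, a stress phosphatase subunit, by -1.87 ± 0.10, ZFP36, which destabilises cytokine messages, by -1.82 ± 0.21, and FOS by -1.49 ± 0.16. Of the cytokines 10 of 20 rose, 3 fell and 7 did not pass (adjusted p = 0.000624 with an estimated correlation). IL32 rose by 5.75 ± 0.33, CCL20 by 5.53 ± 0.29 and CXCL8 by 2.71 ± 0.19, whereas CXCL2, CXCL3 and CXCL1 were at -2.19 ± 0.17, -1.30 ± 0.19 and -1.15 ± 0.19. Of the NF-kB targets 18 of 38 rose, 3 fell and 17 did not pass (adjusted p = 0.0475 with an estimated correlation), with TNFRSF9 up by 3.70 ± 0.24 and CD44 by 2.81 ± 0.18. The 3 that fell were TNFAIP3, NFKBIA and NFKBIZ, at -1.46 ± 0.15, -1.39 ± 0.20 and -1.22 ± 0.19.

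IRF1-associated and antigen presentation genes rose in 13 of 35 members with 0 down (adjusted p = 0.000456 with an estimated correlation). Among them were TAPBP at 1.53 ± 0.13 and B2M, the class I light chain, at 0.79 ± 0.12. Heat shock genes rose in 12 of 19 members and fell in 2 (adjusted p = 0.00137 with an estimated correlation). Also higher at 12 h were CALCB at 3.63 ± 0.29, TNC at 3.31 ± 0.26, the cotransporter gene SLC12A7 at 1.70 ± 0.13, EMP3, a membrane protein, at 1.504 ± 0.13, TMOD1, an actin-capping protein, at 1.502 ± 0.12, and NEDD4L, a ubiquitin ligase, at 1.48 ± 0.11. MAP2K6 and UNC5C were at -1.79 ± 0.21 and -1.69 ± 0.28, both lower at 12 h. LY96 and CD14 rose by 0.67 ± 0.14 and 0.94 ± 0.16, IRF1-AS1 was at -0.74 ± 0.21 (edgeR adjusted p = 0.0120), and TLR4, at -0.05 ± 0.07, did not pass.

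Cytosolic ribosomal protein genes rose in 63 of 74 members, with a median of 0.49 log2 units, but that camera call was lost at adjusted p = 0.250 with an estimated correlation. Across genes, the change from 90 min to 12 h had a Spearman rho of -0.14 with transcript length, and genes are not independent replicates. In cultures numbered 2, 73 of 74 ribosomal protein genes were higher than in those numbered 1. IRF1 was lower at 12 h in all 23 alternatives, from -0.51 to -0.27, but lost the call in 3 (adjusted p from 0.000543 to 0.286), and IRF1-AS1 lost the call in 3 of 22 (0.00248 to 0.209). CXCL2 stayed at -2.12 but lost the call in 1 of 23, with the replicate number as a block (adjusted p = 0.0618, range from 3.00e-122).

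Before LPS, edited and unedited clones had similar mean IRF1 levels, and edgeR found no gene past the threshold. IRF1 was 6.02 ± 1.63 CPM (SD, n = 5 clones) in WT, 6.83 ± 0.498 CPM in HE (n = 3) and 5.54 ± 1.496 CPM in HO (n = 5). The log2 difference from WT was -0.08 ± 0.23 in HO, with a 95% interval of -0.54 to 0.37, and 0.17 ± 0.26 in HE, with an interval of -0.35 to 0.69. IRF1-AS1, at 0.09 ± 0.38 in HO and -0.34 ± 0.45 in HE, and the receptor genes LY96 (0.01 ± 0.27 and -0.47 ± 0.32), CD14 (0.33 ± 0.29 and 0.14 ± 0.34) and TLR4 (0.19 ± 0.80 and -0.21 ± 0.93) did not pass either. edgeR called 0 of 17323 genes for HO, with 375 at an unadjusted p under 0.05, and 0 for HE, with 660. DESeq2 called 0 and 1, the latter ANTXR2, a capillary morphogenesis gene (edgeR -1.43 ± 0.29, adjusted p = 0.979), and limma called 0 in each.

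Mitochondrially encoded genes had a median difference of 0.52 log2 units in HO before LPS, but 0 of 15 members passed. The camera call was lost at adjusted p = 0.674 with an estimated correlation. Over the 3 conditions, mitochondrial reads made up 8.33% ± 1.83 of counts in HO (SD, n = 5 clones), 6.89% ± 0.624 in WT (n = 5) and 6.67% ± 0.804 in HE (n = 3). Without the HO clone 1-C8, at 11.4%, the HO mean was 7.56% ± 0.748 and the list median before LPS was 0.30. In HO the smallest p values belonged to GRASLND (1.85 ± 0.44), ADI1, a methionine salvage enzyme (0.68 ± 0.17), and ENSG00000255366 (2.82 ± 0.78), and in HE also to ITGB7, an integrin (4.10 ± 0.93), and HHIP, a hedgehog-binding protein (-2.45 ± 0.59). Adjusted over the list alone, only DNAJB4, a co-chaperone, passed, at -0.83 ± 0.24 in HE.

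With LPS, IRF1 was above control in 13 of 13 clones at each time, and its level did not differ past the threshold between genotypes. At 90 min it was 19.9 ± 4.69 CPM (SD, n = 5) in WT, 29.6 ± 5.03 CPM in HE (n = 3) and 19.7 ± 10.5 CPM in HO (n = 5). The log2 difference from WT was -0.02 ± 0.27 in HO (95% interval -0.56 to 0.52) and 0.54 ± 0.31 in HE (-0.07 to 1.16, edgeR adjusted p = 0.946). At 12 h IRF1 was 15.8 ± 2.69, 17.2 ± 0.479 and 15.4 ± 5.94 CPM, with differences of -0.03 ± 0.22 in HO and 0.13 ± 0.25 in HE. Of the NF-kB targets, 0 of 36 passed in either genotype at 90 min with edgeR, with medians of 0.08 in HO and 0.23 in HE. At 12 h it was 0 of 37, with medians of 0.04 and 0.07.

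At 90 min edgeR called 0 of 17702 genes for HO, with 646 at an unadjusted p under 0.05, and 0 for HE, with 798. DESeq2 called 2 in HO, ZNF580 (edgeR 1.02 ± 0.21) and PLBD2, a phospholipase-like gene (edgeR 1.14 ± 0.24), and 1 in HE, ZNF440 (edgeR -2.57 ± 0.56), and limma with clone as a random effect called 0 in each. At 12 h edgeR called 0 of 17505 in HO, with 614 at an unadjusted p under 0.05, and 0 in HE, with 438, and DESeq2 and limma called 0. GDF9, a growth factor gene in the list of IRF1's neighbours, had 2 reads over 5 HO clones at 90 min against 68 over 5 WT clones, and passed only when adjusted over the list alone (edgeR log2 -4.65 ± 1.00, adjusted p = 0.00278). In control its reads were 36 in HO and 34 in WT, and at 12 h 35 and 21. Also only adjusted over the list alone, MALAT1, a nuclear RNA, passed at 90 min in HO (-0.73 ± 0.25), and 7 of 15 mitochondrially encoded genes at 12 h, among them MT-RNR1 (0.96 ± 0.29). Of the HO libraries at 12 h, those of 1-C8 held 11.8% and 10.2% mitochondrial reads and 1-F12 replicate 2 held 15.8%. The other HO libraries at 12 h held 5.9% to 8.1%.

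Other genes with the smallest p were ZBTB11 (-1.03 ± 0.22) and DDX6, an RNA helicase (-0.998 ± 0.24), in HE at 90 min. At 12 h they were CPA4, a carboxypeptidase (-2.07 ± 0.46), SIK2, a kinase (-0.95 ± 0.21), and MYRIP (-3.33 ± 0.79) in HO, and NID2, a basement membrane protein (-1.14 ± 0.28), NEK10 (-3.15 ± 0.76) and ZNF423 (-1.99 ± 0.51) in HE. The receptor genes TLR4, LY96 and CD14 passed in neither genotype, at -0.08 ± 0.72, -0.54 ± 0.37 and 0.44 ± 0.39 in HO and 0.18 ± 0.83, -0.14 ± 0.42 and 0.67 ± 0.44 in HE at 90 min. At 12 h they were at 0.15 ± 0.74, -0.22 ± 0.33 and 0.89 ± 0.56 in HO and 0.28 ± 0.85, 0.11 ± 0.38 and 0.48 ± 0.63 in HE. IRF1-AS1 was at 0.12 ± 0.44 and 0.29 ± 0.45 in HO and 0.25 ± 0.50 and 0.15 ± 0.51 in HE. With preset camera, 4, 5 and 7 lists were called for HO at the 3 times and 2, 6 and 4 for HE, and 0 with an estimated correlation, where the lowest adjusted p was 0.317.

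The response comparisons asked directly whether the LPS effect differed between genotypes. IRF1's rise at 90 min was 1.73 ± 0.62 log2 units (SD, n = 5) in WT, 2.09 ± 0.28 in HE (n = 3) and 1.71 ± 0.92 in HO (n = 5), and at 12 h it was 1.41 ± 0.43, 1.33 ± 0.09 and 1.42 ± 0.59. The NF-kB list rose by a mean of 1.19 ± 0.22 in WT, 1.36 ± 0.21 in HE and 1.34 ± 0.37 in HO at 90 min, and by 1.66 ± 0.25, 1.86 ± 0.18 and 1.78 ± 0.48 at 12 h. Cytokines rose by 2.50 ± 0.21, 2.78 ± 0.23 and 2.58 ± 0.58 at 90 min. Over 20 such comparisons of IRF1 and 4 lists, the smallest two-sided exact permutation p was 0.125, for cytokines in HE at 90 min, and the adjusted p was 0.976.

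**Figure D3:**
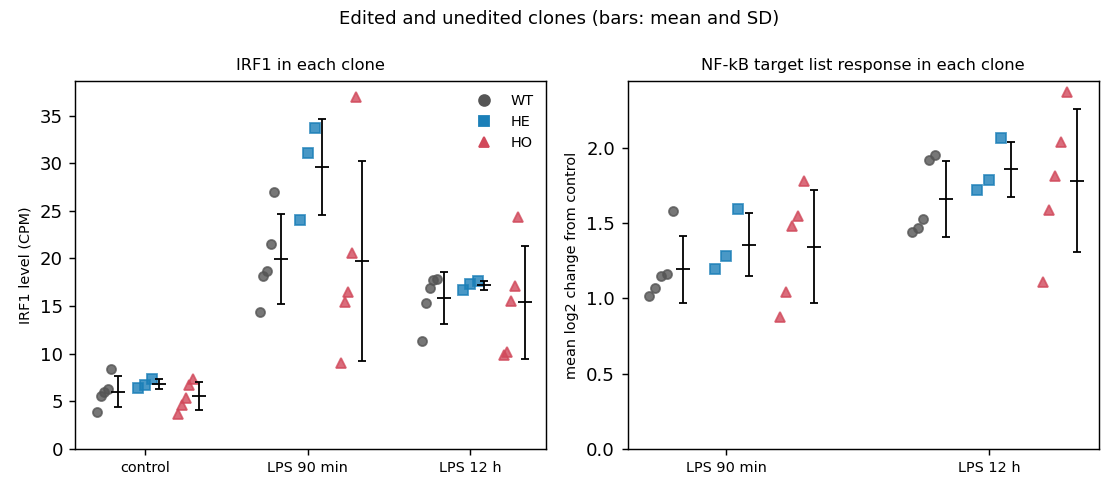
IRF1 level in CPM in each clone (left) and mean log2 change of the NF-kB target list from control in each clone (right), by genotype and time, with the mean and SD of each group. The WT, HE and HO clones overlapped in the NF-kB response, which had means of 1.19, 1.36 and 1.34 at 90 min.

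In edgeR's test of the difference, IRF1's response differed from WT by -0.03 ± 0.30 log2 units at 90 min and -0.02 ± 0.30 at 12 h in HO, and by 0.39 ± 0.34 and -0.03 ± 0.34 in HE. The 95% intervals were -0.62 to 0.56 and -0.61 to 0.56 in HO, and -0.28 to 1.05 and -0.69 to 0.63 in HE. edgeR called 0 of 19526 genes in each of the 4 tests, with 634 and 477 at an unadjusted p under 0.05 in HO and 829 and 856 in HE, while DESeq2 called 0 and 1 in HO and 4 and 6 in HE and limma called 0. Adjusted over the list alone, FOS was the only list member to pass, with a response larger by 1.29 ± 0.35 in HE at 90 min. The response of LY96 differed by -0.59 ± 0.27 and -0.32 ± 0.27 in HO and by 0.29 ± 0.32 and 0.56 ± 0.31 in HE, that of TLR4 by -0.18 ± 0.16 and -0.02 ± 0.16, and 0.33 ± 0.18 and 0.40 ± 0.18. For CD14 the values were -0.03 ± 0.36 and 0.32 ± 0.36 in HO and 0.45 ± 0.41 and 0.47 ± 0.41 in HE, and for IRF1-AS1 -0.04 ± 0.49, 0.12 ± 0.50, 0.64 ± 0.57 and 0.42 ± 0.58, none of which passed.

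Among the genes with the smallest p were NT5C3B (0.60 ± 0.14) and DHX36, a helicase (-0.72 ± 0.18), in HO at 90 min, and PCYT2, a phospholipid enzyme (1.30 ± 0.33), TTC13 (-0.73 ± 0.20) and CPA4 (-1.98 ± 0.53) at 12 h. In HE they were RBBP4P1, a pseudogene (1.64 ± 0.42), ZNF669 (-1.42 ± 0.37) and TRIM26 (-0.72 ± 0.19) at 90 min, and SMOC1, a matrix protein (-1.95 ± 0.44), TCN2, a cobalamin carrier (-2.18 ± 0.53), and ZC3H3 (-1.20 ± 0.30) at 12 h. The HO difference of IRF1's response at 90 min was 0.31 without clone 1-F12, and -0.32 without clone 1-C9. Clone 1-F12 is 1 of the 2 low in TLR4, had a NF-kB list response of 0.87 at 90 min, and had IRF1 at 6.75 CPM in control. Its chromosome 5 genes, the chromosome of IRF1, had a median shift of -0.32 log2 units.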

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

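The tests of chromosome copies, of chromosome 19 in clone 1-C8, of a mislabelled library, of the receptor level and of transcript length between replicate numbers were chosen after the results were seen, and the rule for reading the receptor test was revised after its value was seen.

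Whole chromosomes differed in expression between clones. In 20 of 273 pairs of clone and autosome (21 autosomes with at least 100 genes, 8928 genes) the median gene lay at least 0.2 log2 units from the mean of all clones and beyond 1000 random gene sets, 16 lower and 4 higher, in 11 clones. Chromosome 1 lay beyond the random sets in every clone, from -0.24 in 3-F12 to 0.21 in 1-F9. Its smallest shifts were -0.12 in 1-C12 and 0.12 in 1-C8, and 1-G10 at 0.198 and 1-C9 at -0.194 fell just short of 0.2. On this chromosome the clones thus lay on 2 sides, and the cut decided which were counted, as well as part of the split into lower and higher. Examples were chromosome 20 in 1-F12 (-0.51), chromosome 11 in 2-H1 (-0.47), chromosome 22 in 3-E1 (-0.46) and chromosome 7 in 1-F9 (0.48) and 2-C10 (0.41), and by genotype there were 7 in 5 WT, 4 in 3 HE and 9 in 5 HO clones. A trend over transcript length and GC content is argued against, since removing it kept a median of 99.9% of the shifts, except on chromosome 19 of 1-C8, where 28.6% was kept and that trend may account for most of it, and on chromosome 1 of 1-F9, where 73.8% was kept and the shift went from 0.21 to 0.15; a difference between the replicate numbers is also argued against, since 100% of the shifts were seen in both. Gain or loss of chromosome copies in single clones stays open: a median of 86.2% of a shifted chromosome's genes deviated its way, but choosing pairs by their median largely fixes that share, which was already a median of 73.9% in the 48 other pairs with a shift of at least 0.1.

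TLR4, the LPS receptor gene, was at 4.28 to 12.5 CPM in the HO clone 1-F12 and the WT clone 1-G8 and at 72.2 to 194.7 CPM in the other 11 clones. The NF-kB list response was 0.87 at 90 min and 1.11 at 12 h in 1-F12, and 1.07 and 1.44 in 1-G8, against lowest values of 1.01 and 1.47 in the other clones, while the cytokine response of 1-G8, 2.66 and 3.83, was not low beside the means of all 13 clones, 2.59 and 3.83, and that of 1-F12 was 1.78 and 2.72. The bound set against low depth was met, since 3 of 6 clone libraries of this pair were above the median of their condition. That bound pooled both clones and all conditions, so it cannot decide for 1-F12 with LPS. At 90 min the 1-F12 libraries held 10094510 and 10252375 counts, against a median of 12475294.5 over libraries. Those of 3-E1 were about as shallow, at 10219098 and 11199175, and its NF-kB list response was 1.19. Over the 23 list members with a mean CPM of at least 5, 1-F12 was at 0.76 at 90 min and 0.82 at 12 h. The lowest of the other 11 clones were at 1.29 and 1.65. These values argue against low depth as the reason for the weak NF-kB response of 1-F12. A single mislabelled library is argued against, since 12 of 12 libraries of the pair had TLR4 below the other 66. A lower receptor level may limit the response, but among the other 11 clones Pearson's r of TLR4 with the 90 min response was 0.18 (permutation p = 0.612, adjusted p = 0.787 over 3 relations), Spearman's rho was -0.04 (permutation p = 0.923), and r was -0.32 without the 2 clones farthest from the median. A limit by the receptor level stays open. The bound set against it was that the pair are not the lowest at both times. It was met by 1-G8 at rank 4 at 90 min over all 38 members. Over the 23 with a mean CPM of at least 5, 1-G8 was at rank 2, so the result depends on the members counted. The bound gave no margin, and 1-G8 at 1.07 lay near the lowest other clone at 1.01. The error of a single clone's response was not estimated, and the SD of 0.28 between clones does not measure it.

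Cultures numbered 2 differed from those numbered 1. Of 19526 genes 4655 were higher and 6996 lower in replicate 2, among them 73 of 74 ribosomal protein genes, 57 of 58 nuclear oxidative phosphorylation genes and 15 of 15 mitochondrially encoded genes higher, and 35 of 37 immediate early genes lower. Depth is argued against, since ribosomal protein genes stayed higher by a median of 1.22 ± 0.17 log2 units (SE) in the 15 pairs where replicate 2 was the deeper library. A bias over transcript length may contribute, with a Spearman rho across genes of -0.46 with length and -0.21 with GC content (genes are not independent replicates). No biological explanation was tested.

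IRF1-AS1 in HO clone 1-C8 at 90 min stood apart at 2.44 CPM, against 0.787 to 0.966 in the other HO clones. CD14 in HO clone 1-C9 at 12 h stood apart at 14668 CPM, against 1220 to 4383. GDF9 in HO clone 1-C9 at 90 min was at 0.0483 CPM, against 0 in the other HO clones. The NF-kB list response of WT clone 1-G10 at 90 min stood apart at 1.58, against 1.01 to 1.16. The library of WT clone 1-G10, replicate 2, at 12 h held 11996000 counts, against 16321000 to 21030000 in the group. In 86 groups tested for a sample far from the others 5 had one, and chance gives about 4.3. The LPS effects at 12 h and 90 min differed, in edgeR's test of that difference, by -0.45 ± 0.12 log2 units for IRF1, -0.74 ± 0.21 for IRF1-AS1, 0.67 ± 0.14 for LY96 and 0.94 ± 0.16 for CD14.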

How the results depend on the processing

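Equal weight to both cultures, and leaving out the 2 clones low in TLR4, were chosen after the data were seen. Over the named genes 3334 of 3397 alternative values counted as kept, 29 lost the call, 14 gained it and 20 reversed. Where a gene passed in neither setting, a change of sign smaller than its standard error counted as kept. For such genes, which include those named for genotype, staying below the threshold says little. Of the values behind the 60 rises and falls named with LPS, some in the same gene at several comparisons, 1377 of 1380 kept both. These were chosen as the largest called changes with the same direction in at least 12 clones, so that share was largely fixed by the choice. Of all genes called at 90 min, 21.6% were also called without replicate 2 and 54.7% without replicate 1. Depth limits low genes, such as GDF9 with 2 reads in HO at 90 min.

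The count for LPS at 90 min, 2268, went to 1258 in limma voom on unsummed libraries with clone as a random effect, which changed tool, summing and model together, and to 1271 without the clones low in TLR4, and leaving out a replicate number or a clone gave 506 to 3039, the lowest without replicate 2, where 491 of the 506 genes were shared. At 12 h the count was 2921 and leaving out gave 1720 to 3021, and between the times 4010 and 2114 to 4305. With the replicate block the counts were 2775, 3761 and 4951 for LPS and 0 in all 10 genotype and response comparisons. The replicate numbers were not treated as pairing, since 715 of 741, not all, correlations of clone deviations were above 0.1. That reason is weak, as the lowest correlation was 0.0347 and the median 0.316. Replicate number also had an R2 of 0.80 with the first principal component of the libraries, which held 19.9% of the variance. Summed counts mix the sets by depth, which varied between clones and conditions. At 90 min clone 1-C9 had 23934167 counts in replicate 1 and 7534370 in replicate 2.

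With the DESeq2 Wald test, genotype counts of 0 went to 2 for HO at 90 min, 1 for HE in control, 1 for HE at 90 min, 1 for the HO response at 12 h, and 4 and 6 for the HE response at 90 min and 12 h. C8orf34-AS1, MUC16, ST14 and GRIK5 were among the genes DESeq2 called for the HE response. No DESeq2 fold is given for them, and whether their coefficients converged was not recorded. Without a filter on low counts the genotype counts were 1, 2 and 17 for HO in control, at 90 min and at 12 h, 9 and 3 for HE in control and at 90 min, 2 and 3 for the HO response, and 104 and 22 for the HE response. Equal weight to both cultures called 1 gene for HE at 90 min. For the HE response at 12 h, 1 gene was called without the clones low in TLR4, and 0 to 1 on leaving out, ENSG00000261226 without replicate 2 or without clone 1-H1. With an estimated correlation camera called 4 lists at 12 h and 5 between the times. In the genotype and response comparisons it called 0, as did fry. At 12 h fry also called lists that this camera setting did not, such as the TLR4 pathway components (fry adjusted p = 0.00013). The cause was not tested for any of these.

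On leaving out a replicate number or a clone, LPS values at 90 min ran from -0.0350 to 0.33 for TLR4, -0.35 to 0.38 for CD14 and -1.01 to 0.00972 for ID1, with replicate 1 left out at the reversed end for each. Between the times TLR4 ran from -0.17 to 0.22, and was 0.0271 with clone as a random effect and 0.0355 with equal weight. HO against WT in control ran from -0.32 to 0.25 for IRF1-AS1 and -0.32 to 0.20 for LY96, and at 90 min from -0.33 to 0.28 for IRF1-AS1 and -0.0079 to 0.69 for CD14. HE against WT ran from -0.23 to 0.33 for IRF1 in control and -1.28 to 0.84 for IRF1-AS1 at 90 min. The HO response of IRF1 ran from -0.32 to 0.31 at 90 min and -0.22 to 0.41 at 12 h, and at 12 h that of IRF1-AS1 from -0.47 to 1.17 and that of CD14 from -0.0546 to 0.46. In the HE response at 90 min IRF1-AS1 ran from -0.85 to 1.20 and LY96 from -0.21 to 0.93, and at 12 h IRF1 from -0.33 to 0.71. The cause was not tested.

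List medians also changed sign on leaving out. Mitochondrially encoded genes between the times ran from -0.0577 to 0.51. Ribosomal protein genes ran from -0.0934 to 0.32 for HO at 90 min (-0.0890 with only clones named 1- and -0.0119 without the clones low in TLR4), -0.0044 to 0.51 for HO at 12 h, -0.0650 to 0.61 for HE at 90 min and -0.0851 to 0.40 for the HO response at 12 h. For HE at 12 h NF-kB targets ran from -0.0459 to 0.22 and cytokines from -0.0455 to 0.62. In the HE response immediate early genes ran from -0.0879 to 0.62 at 90 min and mitosis genes from -0.0513 to 0.20 at 12 h. The cause was not tested.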

Other observations

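The relation of TLR4 with the response, and the choice of 11 clones for both relations, came after TLR4 levels and responses were seen, while the expectation for IRF1 was written before its value was seen.

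At 12 h of LPS several gene groups outside the inflammatory lists had members past the edgeR threshold in both directions. Of the p53 targets 2 of 30 rose and 8 fell, with CDKN1A, a cell cycle inhibitor, at 0.62 ± 0.06 log2 units (SE, n = 13 clones) and SESN1, a stress-induced regulator of growth, at -0.59 ± 0.08 (camera adjusted p = 0.219). Of the cholesterol synthesis genes 2 of 27 rose and 8 fell, with IDI1, an isomerase of the pathway, at -0.83 ± 0.10 (adjusted p = 0.133). In the unfolded protein and integrated stress response list 6 of 36 rose and 2 fell, with XBP1, a transcription factor of that response, at 0.71 ± 0.10 and ATF4 at 0.60 ± 0.12 (adjusted p = 0.136). Of the hypoxia and glycolysis genes 8 of 34 rose and 5 fell, with the enolase gene ENO2 at 0.65 ± 0.10 (adjusted p = 0.123). DNA replication genes rose in 7 of 39 members, with RRM2, a ribonucleotide reductase subunit, at 0.55 ± 0.07, a camera call lost at adjusted p = 0.443 with an estimated correlation. Mitosis genes rose in 2 and fell in 4 of 40 (adjusted p = 0.168), with AURKB, a mitotic kinase, at 0.38 ± 0.07. Immediate early genes still rose in 13 of 37 members and fell in 1 (adjusted p = 0.129 with an estimated correlation).

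Histone genes rose in 2 and fell in 5 of 18 members at 12 h, with H4C8 at -0.72 ± 0.15 (adjusted p = 0.123), and of the nuclear RNAs 1 of 5, TUG1, fell by 0.19 ± 0.06 (adjusted p = 0.142). Markers of other cell types were near the floor or mixed, except those of fibroblasts, of which 0 rose and the median was -0.54. Of the lymphocyte markers 1 of 6 rose, IL7R, the IL-7 receptor, by 4.68 ± 0.54 from 22 reads over the 13 clones in control (adjusted p = 0.708), and of the monocyte markers 1 of 4, the integrin gene ITGAM, by 2.13 ± 0.62 (adjusted p = 0.608). Of the epithelial markers ELF3, a transcription factor, rose by 3.81 ± 0.53 and KRT8, a keratin, was at -0.37 ± 0.10 among 10 (adjusted p = 0.881). Of the fibroblast markers 2 of 9 fell, ACTA2, smooth muscle actin, by 0.67 ± 0.10 and COL5A1 by 0.61 ± 0.18, a camera call lost at adjusted p = 0.205 with an estimated correlation. Of the neuronal and embryonic kidney markers 2 of 14 rose and 5 fell, with the homeobox gene HOXA9 at -1.09 ± 0.08 (adjusted p = 0.0766). Ribosomal protein genes rose in 1 of 74 members and mitochondrially encoded genes in 0 of 15, and the camera calls were lost at adjusted p = 0.544 with an estimated correlation for each. Nuclear oxidative phosphorylation genes rose in 2 and fell in 2 of 58 (adjusted p = 0.617).

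One hypothesis was that clones with more IRF1 before LPS respond more. Among the 11 clones other than those low in TLR4, Pearson's r of IRF1 in control with the NF-kB response at 90 min was -0.65 (permutation p = 0.0331, adjusted p = 0.0993 over 3 relations), opposite to the expected direction, and Spearman's rho was -0.47 (permutation p = 0.146). Without the 2 clones farthest from the median r was -0.32, so the relation rests on those clones. The same control library also enters both values, with opposite sign in the response. Noise in it can push r below 0 with no relation present, and the permutation does not allow for this. The sign and p of r therefore cannot decide how IRF1 level relates to the response. For TLR4 with the response at 12 h r was -0.09 (permutation p = 0.787) and rho 0.04 (permutation p = 0.924).

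Other splits of the clones were counted beside each comparison. For LPS, chance can be excluded, since 1 of 100 splits, the real one, gave as many genes as the real 2268, 2921 and 4010, and the highest other splits gave 152, 212 and 1. For genotype the real counts were 0 with edgeR (375, 646 and 614 genes at an unadjusted p under 0.05 in HO, 660, 798 and 438 in HE), so 100 of 100 splits are as large whatever the data, and the count of splits says nothing about chance. Of these splits 2, 7 and 4 called any gene for HO in control, at 90 min and at 12 h, and 2, 4 and 5 for HE. The highest other splits gave 1, 317 and 5 genes for HO in control, at 90 min and at 12 h, and 54, 504 and 35 for HE. For the response the real counts were also 0, so 60 of 60 splits are as large by construction. There 2 and 1 splits called any gene for HO and 3 and 4 for HE, with highest counts of 1373 and 1 and of 1522 and 2. Why a few splits call many genes was not tested.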
